A study of Mus musculus with 10 samples.

How the data were processed

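The series measured where HA-tagged SOX2 and SOX15 sit on chromatin in mouse embryonic stem cells grown in 2i/LIF, a medium that holds the cells in the naive state. Each factor carried its tag from its own knock-in locus, per the labels. Chromatin crosslinked with formaldehyde was sheared and precipitated, and the DNA was sequenced (ChIP-seq). The 10 samples comprise 2 SOX2 and 3 SOX15 ChIP libraries and 5 input libraries, 2 for SOX2 and 3 for SOX15. Groups and replicate numbers came from the titles. The peak lists of the 5 ChIP libraries were analysed; values of the inputs were not analysed here. The labels do not say whether replicates were separate cultures, so differences between them may be technical.

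Bowtie2, MACS2, deepTools and the genome build mm10 are named in the submitters' processing notes, without versions. Each deposited list belongs to 1 sample, so peaks were called per sample. For each peak the authors deposited a fold enrichment (a linear ratio over background), a −log10 p-value, a −log10 q-value, the offset of the summit and an integer score. The deposited score equalled 10 times the −log10 q-value, rounded down, in every one of the 5 lists. The fold is the authors' own value per peak and was used to describe, rank and filter peaks within a list. Folds are comparable only within a list. Means over libraries, and SOX15 folds given beside SOX2 folds, therefore describe the lists and do not compare the strength of binding. The smallest −log10 q-value in the deposited lists was 2.10 and 2.20 for SOX2 replicates 1 and 2, and 2.76, 2.03 and 1.31 for SOX15 replicates 1, 2 and 3, so the list of SOX15 replicate 3 reaches to weaker peaks. Whether inputs served as the control in peak calling is not given in the sources used here. The lists give no read counts, so the depth of each library is unknown, and a locus without a peak may lie under the caller's threshold. Reads of near-identical gene copies, such as the U1, U2 and U3 RNA genes, can map to several places, so the share of signal at each copy is uncertain.

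Peaks of 1 factor were merged where they overlapped by at least 1 bp. A region was called reproducible when both SOX2 libraries, or at least 2 of the 3 SOX15 libraries, had a peak in it. Overlaps were counted with bedtools 2.31.1. The background was 1000 random placements of the same intervals on their own chromosomes, each taken as 1 to the largest peak end, with a one-sided empirical p whose smallest value is 0.001. Shares carry Wilson 95% intervals, which cover counting error alone. Differences of median log2 fold between peaks of 1 library were tested with two-sided permutation tests of 100000 resamples (smallest p 1e-05). Calls of replicate 3 peaks in the other SOX15 libraries were compared between peaks on SOX2 regions and peaks on no SOX2 peak, away from snRNA, snoRNA and histone genes, by permutation within bins of fold. Shares of regions and genes were compared with two-sided Fisher's exact tests, and paired calls on the same regions with exact McNemar tests, with Benjamini-Hochberg adjustment within each family. Regions, peaks and genes are not independent replicates, so these p-values describe the libraries at hand. A permutation of 2 against 3 libraries has 10 splits and cannot give an exact p below 0.1, and tests that assume a distribution were not used on so few values, so values per library were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

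Genes came from the RefSeq table of GRCm38.p6, which shares its coordinates with mm10; 21631 protein-coding genes on the 20 chromosomes with peaks were used. The table gives the start and end of a gene and no strand. Distances planned from the transcription start were therefore measured from either gene end (1 kb, for the share of regions at promoters) or from the gene body (50 kb, for gene lists). A summit near a gene end can thus lie at the 3′ end. The 20 gene lists were fixed before the data were examined, and 331 of their 332 entries were found. Each list was compared with the other protein-coding genes, with adjustment over the 20 lists of a factor. The planned search for SOX and other sites in the DNA sequence was not run, because no genome sequence was used here.

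Named genes followed a rule fixed before the data were examined. It took the gene nearest to the 10 highest-ranked reproducible regions of each factor, by mean percentile rank of fold within the libraries. It added up to 30 list members with a reproducible SOX15 region, up to 15 list members with a SOX2 region and no SOX15 peak, and the genes nearest to up to 10 SOX15 regions with no SOX2 peak. Sox15, Sox2, Pou5f1, Nanog, Klf4, Esrrb, Hand1 and Foxk1 were always reported. The classes of small nuclear RNA (snRNA), small nucleolar RNA (snoRNA), clustered histone and ribosomal protein genes, and the individual genes named under them, were chosen after their values were seen, as were the tests on SOX2 regions away from these classes. A region was put in a class when it lay within 1 kb of such a gene. Where several classes applied, the first was taken in the order snRNA, clustered histone, snoRNA and ribosomal protein. The small RNA classes follow the RefSeq annotation. It lists the U3 genes, Rnu3a and Rnu3b1 to Rnu3b4, as snRNA, although U3 acts in ribosomal RNA processing.

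The procedures were tested on simulated data. With 5% of 200 regions planted on SOX2 regions, 20 of 20 simulations passed the threshold of 0.05; with 0% planted, 2 of 20 did. A list with 10 of its 20 genes given a region was called in 20 of 20 simulations, and in 0 of 20 when no gene was given one. Those calls used the exact test without adjustment over lists. Smaller shares, such as the 4 of 18 housekeeping genes near SOX15 regions, were not simulated. With 100 of 1000 peaks shifted by 0.5 in log2 fold the difference was called in 20 of 20 simulations, and with no shift in 2 of 20; the smallest groups of peaks compared here, of 18, are below that size. Alternatives covered stricter q-values, other overlap rules, other definitions of a reproducible region, other distances, local placement and leaving out each library.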

Results

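HA-tagged SOX2 and SOX15 were mapped by ChIP-seq in mouse embryonic stem cells, to find where each of these related HMG-box transcription factors binds. SOX2 is a core factor of pluripotency. The SOX2 libraries held 2676 and 4817 peaks in replicates 1 and 2 (mean 3746.5 ± 1514, SD, n = 2). The SOX15 libraries held 217, 672 and 437 peaks in replicates 1, 2 and 3 (mean 442 ± 228, SD, n = 3), so each SOX15 list was shorter than either SOX2 list. Median peak width was 304 and 331 bp for SOX2, and 486, 255.5 and 300.0 bp for SOX15. Depth is unknown, and no exact test of 2 against 3 libraries can go below p = 0.1.

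Replicate lists of SOX2 shared most of the shorter list. Of the SOX2 replicate 1 peaks 88.8% (95% interval 87.6 to 90.0) overlapped a replicate 2 peak, and 49.2% of the replicate 2 peaks overlapped replicate 1. Among SOX15 lists the share ranged from 23.7% (replicate 2 in replicate 1) to 73.7% (replicate 1 in replicate 2). Each share exceeded every one of 1000 random placements (permutation p = 0.001, the smallest they can give). Merging gave 5115 SOX2 regions, of which 2369 were in both libraries, and 967 SOX15 regions, of which 200 were in at least 2 libraries and 120 in each of the 3. SOX15 replicate 2 had 471 regions that neither other SOX15 library called.

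The strongest SOX15 peaks lay at genes for small RNAs of splicing and RNA processing. Of the 25 peaks with the highest fold enrichment, 21, 23 and 23 in SOX15 replicates 1, 2 and 3 lay within 1 kb of an snRNA gene, against 4 and 0 in SOX2 replicates 1 and 2. One more in each SOX15 library lay at a snoRNA gene. Of the 15 snRNA genes with a name that starts in Rnu, 11 had a peak in each of the 3 SOX15 libraries and in both SOX2 libraries. Of all 1003 snRNA genes in the table, most of them without such a name, 34 (3.39%) had a reproducible SOX15 region within 1 kb and 35 (3.49%) a SOX2 region. At Rnu3b1 (chromosome 11, 87443237 to 87443451), a gene for the U3 RNA of ribosomal RNA processing, the deposited fold was 48.1, 52.8 and 72.7 in the SOX15 libraries and 41.2 and 20.8 in the SOX2 libraries. At Rnu2-10 (chromosome 11, 101658238 to 101658424), a gene for the spliceosomal U2 RNA, it was 25.1, 48.0 and 46.0 for SOX15 and 29.3 and 32.8 for SOX2. Rnu7 (chromosome 6, 124741225 to 124741286), whose RNA acts in histone mRNA 3′ end formation, had 13.6, 31.9 and 28.2 for SOX15 and 21.5 and 15.1 for SOX2. Rnu6, Rnu1b1, Rnu1b2 and Rnu1b6 had no peak in the 5 libraries. These genes were chosen after their values were seen, and reads shared between their copies leave the values at single copies uncertain.

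The regions named by rank were of the same kind. The 10 highest-ranked SOX15 regions had Trappc6b, Tmem107, Tex14 (2 regions), Kif2c, Sirt4, Igdcc3, Gtf3c6, Pecr and Hhat as nearest protein-coding genes, and each lay within 1 kb of an snRNA or snoRNA gene. The region near Tmem107 (chromosome 11, 69073158 to 69074043) covered Snord118, the gene of the U8 RNA, with a fold of 54.6 ± 1.82 in the SOX15 libraries (SD, n = 3). The region near Trappc6b (chromosome 12, 59040043 to 59041369) had 61.6 ± 12.5 (SD, n = 3). Both were also called in SOX2 replicates 1 and 2, with folds of 28.5 and 13.2 near Tmem107 and 44.7 and 14.3 near Trappc6b. The 10 highest-ranked SOX2 regions were near Abca4, Vwa3b, Akr1d1, Sptlc2, Prune2, Mgat4e, Kcnh8, Ephb1, Tenm3 and Epb41l4a. None of these 10 lay within 1 kb of such a gene. The first, inside Abca4 (chromosome 3, 122145268 to 122145901), had folds of 60.6 and 47.3 in the SOX2 libraries and 6.17 in SOX15 replicate 3. SOX15 replicate 3 also had a peak at the regions of Vwa3b, Akr1d1, Sptlc2, Mgat4e, Kcnh8, Ephb1 and Tenm3. Those of Prune2 and Epb41l4a had no SOX15 peak, and SOX15 replicates 1 and 2 had none at any of these regions.

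**Figure D1:**
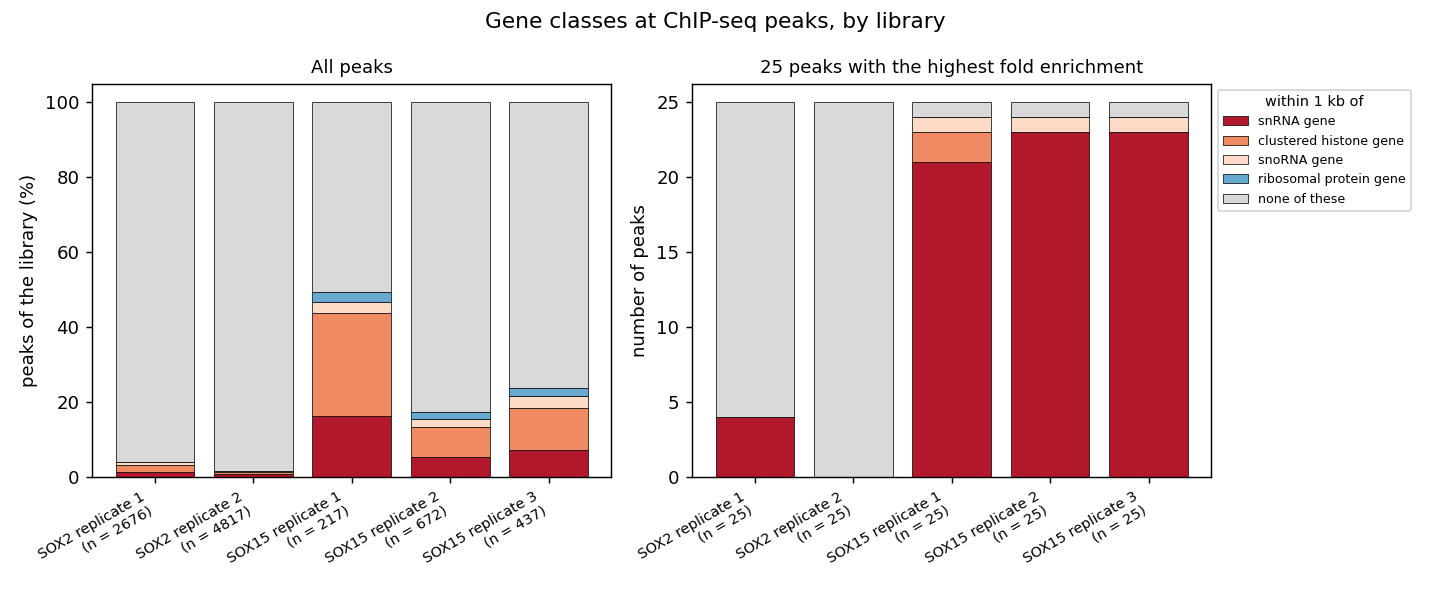
Gene classes at the peaks of the 5 ChIP libraries, as percent of a library's peaks (left) and as number among its 25 peaks of highest fold enrichment (right); colours stand for the class of gene within 1 kb. In SOX15 replicates 1, 2 and 3, 21, 23 and 23 of those 25 lay at snRNA genes, against 4 and 0 in SOX2 replicates 1 and 2.

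Histone gene clusters formed the largest named class of reproducible SOX15 regions. Of the 200 regions 54 (27.0%, interval 21.3 to 33.5) lay within 1 kb of a clustered histone gene on chromosome 13 or 3, 32 (16.0%) at snRNA genes, 10 (5.0%) at snoRNA genes, 7 (3.5%) at ribosomal protein genes and 97 (48.5%) at none of these. Of randomly placed regions 0.03% lay near a clustered histone gene. Of the 63 clustered histone genes 51 (81.0%) had a reproducible SOX15 region within 1 kb, against 0.473% of other protein-coding genes (Fisher's exact test, adjusted p = 1.8e-101). SOX2 regions were near 24 of the 63 (38.1%), against 4.55% of other genes (Fisher's exact test, adjusted p = 4.3e-16). Neighbouring histone genes share regions, so genes are not independent in these tests. A SOX2 region needs a peak in both SOX2 libraries, and these differed: replicates 1 and 2 had 49 and 23 peaks in the histone class. SOX15 replicates 1, 2 and 3 had 60, 55 and 49. Chromosome 13 held 25.8%, 10.3% and 12.4% of the SOX15 peaks, and 6.02% and 5.02% of the SOX2 peaks. At H1f3, a linker histone gene (region on chromosome 13, 23554895 to 23555345), the SOX15 fold was 15.8 ± 4.08 (SD, n = 3), and this region had no SOX2 peak. A neighbouring SOX15 region at H1f3 did have SOX2 peaks, with folds of 12.95 and 5.24.

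**Figure D2:**
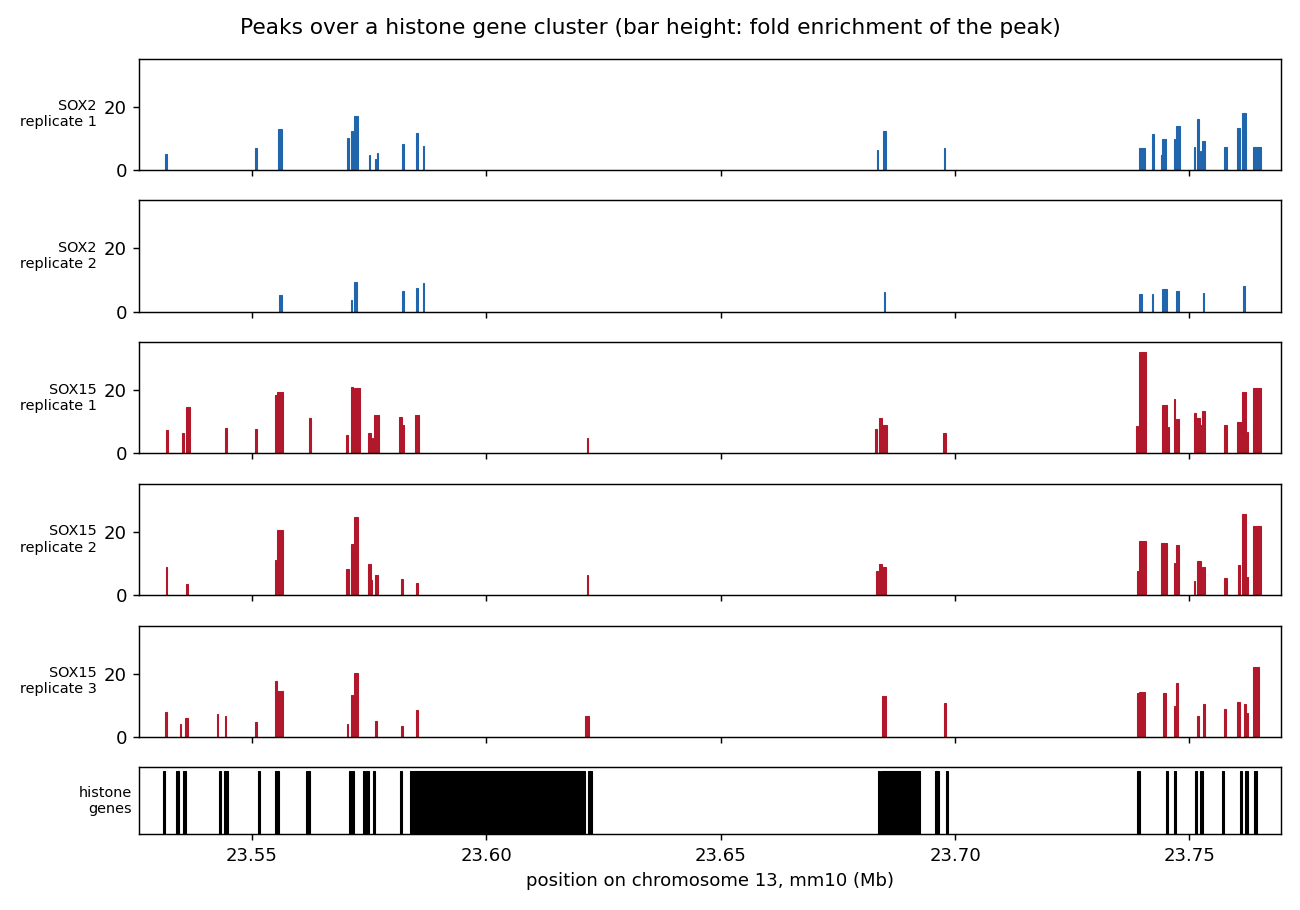
Peaks of the 5 ChIP libraries over a cluster of histone genes on chromosome 13 (mm10), drawn to scale; each bar spans a peak, its height is the deposited fold enrichment, and black boxes are histone genes, the 2 long ones being the table's models of H2bc6 and H2bc4. The window (23526044 to 23769412) holds 29 histone genes, and SOX15 replicates 1, 2 and 3 had 37, 29 and 29 peaks in it, against 29 and 13 in SOX2 replicates 1 and 2.

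SOX15 regions overlapped SOX2 regions far more often than random placement gives, although most SOX2 regions had no SOX15 peak. Of the 200 reproducible SOX15 regions 73 (36.5%, interval 30.1 to 43.4) overlapped a reproducible SOX2 region, against 0.14% on average in random placements (permutation p = 0.001, the smallest they can give). In the other direction 75 of 2369 SOX2 regions (3.17%, interval 2.53 to 3.95) overlapped a reproducible SOX15 region, and 190 (8.02%) overlapped a peak of any SOX15 library, 115 of them in replicate 3 alone. A peak of at least 1 SOX2 library was present at 132 SOX15 regions (66.0%), which left 68 without one. SOX2 replicate 1 covered 131 of the 200 SOX15 regions and replicate 2 covered 76, with 56 in replicate 1 alone and 1 in replicate 2 alone (exact McNemar test, p = 8e-16), although replicate 2 had more peaks. Without SOX2 replicate 2 the share of SOX15 regions was therefore 65.5%, and the share of SOX2 regions was 5.49%; without SOX2 replicate 1 the latter was 1.64%. Away from snRNA, snoRNA and histone genes, 20 of 104 SOX15 regions (19.2%) and 21 of 2311 SOX2 regions (0.909%) overlapped. Of the SOX15 regions 8 (4.0%) overlapped the 200 strongest SOX2 regions.

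The classes of gene differed in how often SOX2 libraries called them. Of the 32 SOX15 regions at snRNA genes 31 (96.9%, interval 84.3 to 99.4) had peaks in both SOX2 libraries. At clustered histone genes 20 of 54 (37.0%, interval 25.4 to 50.4) had both and 42 had at least 1, and this lower share rests on SOX2 replicate 2, which called 21 while replicate 1 called 41. At ribosomal protein genes 2 of 7 had a peak in 1 SOX2 library and 0 in both. The 10 highest-ranked SOX15 regions with no SOX2 peak were near H1f3, H2bc18, Pdgfrb, H2bc4, Zmynd8, H1f2, Gtf2a1, H3c15, Pkp2 and Ggcx; 4 of these are within 1 kb of a clustered histone gene. This holds for these regions alone, since H1f3, H2bc4, H1f2 and H2bc18 have other regions with peaks in both SOX2 libraries. At the region in Pdgfrb, a growth factor receptor gene of mesenchymal cells (chromosome 18, 61064982 to 61065434), the SOX15 fold was 11.6 ± 3.06 (SD, n = 3).

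SOX15 regions with and without SOX2 lay close to an end of a protein-coding gene more often than SOX2 regions did. A summit within 1 kb of a gene end was found at 34 of 73 regions of both factors (46.6%), 34 of 68 SOX15 regions with no SOX2 peak (50%) and 92 of 2179 SOX2 regions with no SOX15 peak (4.22%). Either SOX15 class differed from the SOX2 class (Fisher's exact tests, adjusted p = 9.1e-26 without SOX2 and 1.5e-24 with SOX2), and the SOX15 classes showed no difference past the threshold (adjusted p = 0.98). Without regions at snRNA, snoRNA and histone genes the difference from the SOX2 class fell from 42.4 to 25.8 points for regions of both factors (Fisher's exact p = 0.00016), and from 45.8 to 35.4 points for SOX15 without SOX2 (exact p = 8.4e-15). Random placement gave 3.2% for SOX15 and 3.02% for SOX2 regions. The gene table has no strand, so starts and ends of genes cannot be separated here.

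Within the SOX15 lists, peaks on SOX2 regions were the stronger ones. Their median log2 fold exceeded that of the other peaks by 1.36, 2.02 and 0.36 in replicates 1, 2 and 3 (permutation tests, each p = 1e-05, the smallest they can give). Without peaks at snRNA, snoRNA and histone genes the differences were 0.42, 0.83 and 0.24, and without SOX2 replicate 2 they were 0.88, 0.93 and 0.39. Within the SOX2 lists, peaks on reproducible SOX15 regions differed from the rest by -0.09 in replicate 1 (permutation p = 0.10) and -0.14 in replicate 2 (permutation p = 0.13), neither past the threshold. Without peaks at snRNA, snoRNA and histone genes they were -0.36 (permutation p = 0.00042) and -0.53 (permutation p = 0.0026), which pass it. The sign of the SOX2 difference was not stable: with SOX15 regions of any library it was 0.42 and 1.1 (permutation p = 1e-05 each), and without SOX15 replicate 3 it was 0.05 and 0.04. Single SOX15 libraries, with snRNA, snoRNA and histone genes left out, gave -0.38, -0.39 and 0.67 in SOX2 replicate 1 for SOX15 replicates 1, 2 and 3, and -0.50, -0.53 and 1.58 in SOX2 replicate 2 (permutation tests, largest adjusted p = 0.0072).

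SOX15 replicate 3 stood apart at SOX2 regions away from snRNA, snoRNA and histone genes. It had a peak at 132 of these 2311 regions, against 19 in replicate 1 and 19 in replicate 2 (exact McNemar tests, adjusted p = 3e-30 and 5.8e-31); 114 were called in replicate 3 alone. Among the strongest decile of SOX2 regions, replicate 3 had a peak at 73 of 224 (32.6%, interval 26.8 to 39.0), replicate 1 at 1 and replicate 2 at 0. The SOX2 region upstream of Pou5f1, the gene of the SOX2 partner OCT4 (chromosome 17, 35503744 to 35504395), was among them, with folds of 29.97 and 47.0 in the SOX2 libraries and 11.8 in SOX15 replicate 3. At the 99 SOX15 regions of any library near snRNA or histone genes, replicates 1, 2 and 3 called 91, 86 and 79. The list of replicate 3 reaches to weaker peaks, with a smaller minimum of −log10 q than the others, and 108 of the 114 sites reached the larger of the minimum −log10 q values of the other SOX15 lists.

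**Figure D3:**
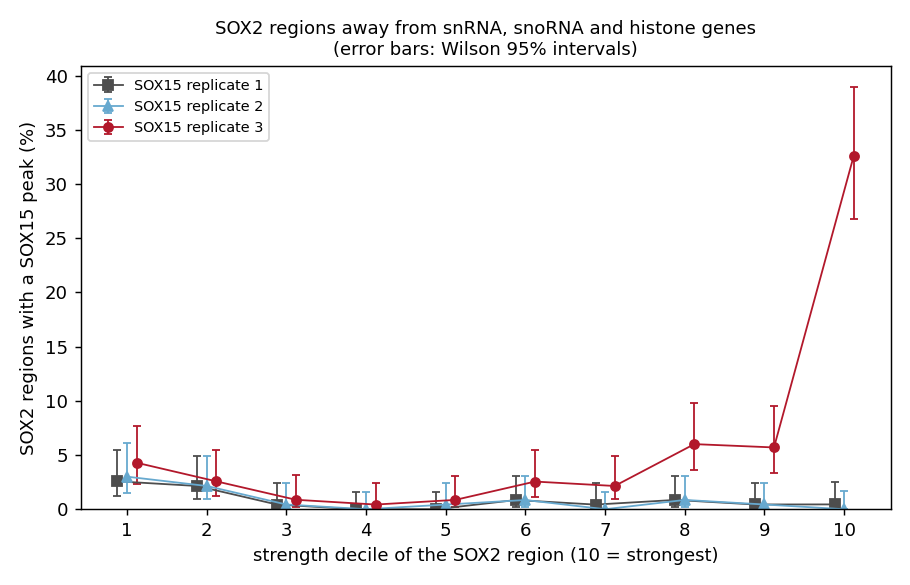
Percent of reproducible SOX2 regions, away from snRNA, snoRNA and histone genes, that overlap a peak of each SOX15 library, by decile of SOX2 strength (x axis, 10 is strongest); points are shares and bars are Wilson 95% intervals. In the strongest decile replicate 3 reached 32.6%, while replicates 1 and 2 had 1 and 0 of 224 regions.

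SOX2 regions gathered near genes of pluripotency. Of 18 naive pluripotency genes 16 had a reproducible SOX2 region within 50 kb, against 14.1% of other genes (Fisher's exact test, adjusted p = 6e-11), as had 10 of 15 core pluripotency genes (adjusted p = 4.9e-05) and 9 of 19 SOX family genes (adjusted p = 0.0037). The formative and primed list (7 of 18), the WNT pathway (7 of 18) and the LIF and JAK-STAT pathway (6 of 14) also passed, each with adjusted p = 0.029 in Fisher's exact test. Neuroectoderm (6 of 16, adjusted p = 0.052), TGF-beta and BMP (6 of 17, 0.062), chromatin regulators (6 of 20, 0.12) and FGF and ERK (5 of 16, 0.13) did not pass the exact test. Neither did housekeeping (4 of 18), trophectoderm (3 of 18), germline (3 of 18), skeletal muscle (2 of 16), fibroblast (2 of 14), blood (2 of 15), primitive endoderm (1 of 16), mesoderm (1 of 16), 2-cell-like (0 of 14) or liver genes (0 of 15). In place of 6 lists, 2 passed within 100 kb, 3 without SOX2 replicate 1 and 9 with the nearest gene alone. The SOX family, the formative and primed list and the LIF and JAK-STAT pathway did not pass within 100 kb (exact tests, adjusted p = 0.074, 0.092 and 0.074) or without SOX2 replicate 1 (adjusted p = 0.072, 0.070 and 0.0503), nor the WNT pathway within 100 kb (adjusted p = 0.092).

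Many of these SOX2 sites had no SOX15 peak nearby. Of the list members 94 had a SOX2 region and 66 of those had no peak of any SOX15 library within 50 kb. The 15 highest-ranked were Rif1, Sox2, Lifr, Tcf7l1, Tead1, Foxd3, Prdm14, Id3, Jarid2, Tgif1, Klf4, Smad7, Nes, Suz12 and Etv5. Downstream of Sox2 itself (chromosome 3, 34653762 to 34654340) the fold was 33.3 and 35.3 in the SOX2 libraries. Near Lifr, the LIF receptor gene (chromosome 15, 7081796 to 7082357), it was 32.4 and 29.9, and at Tcf7l1, a repressor of WNT target genes (chromosome 6, 72787291 to 72787866), 25.9 and 44.0.

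SOX15 regions were near 12 list members, and the housekeeping list was the one that passed. It had 4 of 18 genes (Polr2a, Eef1a1, Gapdh and Eif4a2), against 2.25% of other genes (Fisher's exact test, adjusted p = 0.012). The highest-ranked region of each also had a peak in SOX2 replicate 1, with folds of 22.8, 8.71, 7.48 and 11.2 in that order. SOX2 regions were near 4 of the 18 genes as well, against 14.2% of other genes. Whether these peaks are background was not tested. Naive pluripotency had 3 of 18 (Tfcp2l1, Zfp42 and Esrrb; exact test, adjusted p = 0.073). It passed the exact test within 10 kb (adjusted p = 0.009), with the nearest gene alone (adjusted p = 0.003) and without regions at snRNA, snoRNA and histone genes (adjusted p = 0.030), and did not within 100 kb (adjusted p = 0.22). Without SOX15 replicates 1, 2 and 3 in turn its share fell from 16.7% to 11.1%, 5.56% and 11.1% (exact tests, adjusted p = 0.46, 0.88 and 0.37). Core pluripotency (Trim28), the SOX family (Sox15), mesoderm (Cdx1), fibroblast (Pdgfrb) and blood (Csf1r) had 1 gene each, the last 3 sharing 1 region, and the other 13 lists had 0. Folds in SOX15 replicates 1, 2 and 3 were 8.35, 17.6 and 9.37 at Polr2a, the gene of the large subunit of RNA polymerase II (region on chromosome 11, 69758184 to 69758845), and 11.1, 7.27 and 7.62 near Zfp42, also called Rex1 (chromosome 8, 43286804 to 43288445).

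Of the genes fixed for reporting, Esrrb and Sox15 had a reproducible SOX15 region. In Esrrb, a naive pluripotency factor, SOX15 folds were 7.67 and 6.27 in replicates 1 and 2 (region on chromosome 12, 86502708 to 86503656); the strongest SOX2 peaks in the gene, with folds of 38.1 and 35.6, started at 86501424 and 86501394 on the same chromosome, outside that region. SOX15 replicate 3 had a peak on that SOX2 site, with a fold of 6.43. The region near Sox15 (chromosome 11, 69671956 to 69672472) had folds of 4.96 and 6.51 in SOX15 replicates 2 and 3 and lay inside Eif4a1. At Nanog, SOX2 folds were 6.76 and 10.4 at the gene's edge, and SOX15 replicate 3 had 3 peaks within 50 kb while replicates 1 and 2 had 0. Sox2 and Klf4 had peaks in both SOX2 libraries and in no SOX15 library. Foxk1 had 1 peak, in SOX2 replicate 2 (fold 6.0), and Hand1 had no peak in the 5 libraries.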

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

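The difference of median log2 fold between peaks with and without the other factor went opposite ways in the 2 groups. It was negative in both SOX2 libraries (mean -0.12 ± 0.03, SD, n = 2) and positive in the 3 SOX15 libraries (mean 1.25 ± 0.83, SD, n = 3), which puts the SOX15 mean 1.37 above the SOX2 mean. The difference between the groups was not tested: a permutation of the libraries cannot give an exact p below 0.1 with 2 against 3, and tests that assume a distribution were not used on so few values. The 2 SOX2 values did not pass their own permutation tests, and alternatives passed in both directions. Without snRNA, snoRNA and histone genes they were -0.36 (permutation p = 0.00042) and -0.53 (p = 0.0026). With SOX15 regions of any library they were 0.42 and 1.1 (permutation p = 1e-05 each), and with those of every library replicate 1 gave 0.20 (p = 0.0056).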

How the results depend on the processing

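Among the alternatives, those with one common q-value minimum, without snRNA, snoRNA and histone regions, and with libraries left out of the fold comparisons and of the SOX15 replicate overlaps, were chosen after seeing the data. Numbers of gene lists past the threshold aside, 133 of 155 recomputed values kept direction and side of the threshold. Overlap shares, differences at gene ends and SOX15 fold differences kept both under each alternative run. Among them, the difference at gene ends for regions of both factors fell from 42.4 to 25.8 points without snRNA, snoRNA and histone regions, and the share of SOX15 regions on SOX2 regions ranged between 4.0% (the 200 strongest SOX2 regions) and 65.5% (without SOX2 replicate 2). Leaving out scaffolds and the mitochondrial genome removed no peak, so those values, which are part of the 155, could not change.

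Without snRNA, snoRNA and histone genes the SOX15 fold difference fell from 1.36 to 0.42 in replicate 1. In SOX15 replicates 2 and 3 it fell from 2.02 to 0.83 and from 0.36 to 0.24. The SOX2 fold difference was the one that changed sign under alternatives. In SOX2 replicate 1 its main value of -0.09 became 0.064 with −log10 p, 0.079 with −log10 q of at least 5, 0.42 with SOX15 regions of any library, 0.20 with those of every library and -0.36 without snRNA, snoRNA and histone genes. Leaving out SOX15 replicates gave -0.022 to 0.14, and the 0.14, without SOX15 replicate 2, passed (permutation p = 0.042). In SOX2 replicate 2 the main value of -0.14 became 0.011 with −log10 q of at least 5, 1.1 with any library and -0.53 without those genes. Leaving out SOX15 replicates gave -0.21 to 0.040, and the -0.21, without SOX15 replicate 1, passed (permutation p = 0.022). In tests against single SOX15 libraries, without those genes and also chosen after seeing the data, replicates 1 and 2 gave negative values and replicate 3 positive ones (0.67 and 1.58), so the turn with any library goes with SOX15 replicate 3. What turned the sign under the other alternatives was not tested. The number of SOX15 lists past the threshold went from 1 to 2 within 10 kb, with the nearest gene and without those genes, and the number of SOX2 lists from 6 to 2 within 100 kb, to 9 with the nearest gene, to 7 with −log10 q of at least 5 and without those genes, and to 3 and 7 without SOX2 replicates 1 and 2. Without SOX15 replicate 2 the SOX15 share of naive genes fell from 16.7% to 5.56%.

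SOX2 and SOX15 libraries share replicate numbers 1 and 2 by name alone, which is too few to show pairing. Taken as a replicate block, same-numbered pairs shared 35.2% of SOX15 peaks with SOX2 on average and differently numbered pairs 27.3%. Alternatives for the SOX motif share were not run, because no genome sequence was used here. Depth is unknown, so weak sites of a shallow library cannot be told from unbound ones.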

Other observations

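The tests below, with their bounds, were chosen when most of the deciding values had been seen, except that of overall sensitivity in the last paragraph, whose bound was set before the data were examined. The comparison by bins of fold was looked at with several numbers of bins, and with bins of q-value, before its bound was set. Its results with bins of q-value are not given here.

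Malat1 and Hsp90ab1 are given as single genes picked after their values were seen. At Malat1, a nuclear long noncoding RNA gene (chromosome 19, 5795690 to 5802672), the fold was 12.8, 12.5 and 13.6 in the SOX15 libraries and 10.3 and 5.59 in the SOX2 libraries. Hsp90ab1, a chaperone gene (chromosome 17, 45567778 to 45573261), had 13.1, 12.998 and 11.9 for SOX15 and 6.28 in SOX2 replicate 1. Ribosomal protein genes had a reproducible SOX15 region within 1 kb at 6 of 84 (7.14%), among them Rpl3, Rps18 and Rpl36 in each of the 3 libraries. Of other protein-coding genes, with clustered histone genes left out, 0.447% had one (Fisher's exact test, adjusted p = 3.9e-06). At Rpl3, 1 of the 2 regions also lay at a snoRNA gene. SOX2 regions were near 0 of the 84.

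The SOX2 regions called in SOX15 replicate 3 were set against the other genes with a SOX2 region within 50 kb, since SOX2 regions as a whole gather near some of the lists. For the 132 regions no list passed (Fisher's exact tests): 4 of 9 SOX family genes (Sox13, Sox15, Sox18 and Sox21; adjusted p = 0.057), 3 of 4 housekeeping genes (adjusted p = 0.054) and 3 of 16 naive pluripotency genes (Esrrb, Jam2 and Tet2; adjusted p = 0.85). For the 114 called in replicate 3 alone the SOX family passed, with the same number of genes (exact test, adjusted p = 0.038), and no other list did. Sox13 and Sox21 were the genes nearest to their sites. The site counted for Sox15 lay 47377 bp away and nearer to Tnfsfm13.

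The snRNA regions may be chromatin that comes down whatever factor carries the tag. Of the SOX15 regions at snRNA genes 96.9% were called in both SOX2 libraries as well, which goes with precipitation by the antibody or of heavily transcribed chromatin, and also with binding by both factors. Other small RNA genes lacked such regions: 0 of 200 SOX15 and 1 of 2369 SOX2 regions lay within 1 kb of a transfer RNA gene. Rn7sk, also listed as snRNA, had no peak in any library. Transcription was not measured here, so these values cannot decide between the explanations. For binding by SOX15 without SOX2, 31 of the 32 regions had peaks in both SOX2 libraries, against the bound set for it. Those SOX2 peaks may themselves be background, so this cannot decide whether SOX15 binds there without SOX2. At histone genes the share was 37.0%, between the bounds set for the explanations, and it rests on SOX2 replicate 2, which called 21 of the 54 regions while replicate 1 called 41, so background and binding by SOX15 cannot be told apart there. A library from untagged cells was not used here, and SOX sites in the DNA were not searched.

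The SOX2 sites called in SOX15 replicate 3 alone could be technical or could be SOX15 binding that replicates 1 and 2 missed. Of the sites 94.7% reached the larger of the minimum −log10 q values of the other lists. This argues against the lower cut-off of the replicate 3 list alone as the cause. It does not cover the q-values as a whole, which were lower in that list. Median −log10 q was 6.34 in replicate 3 (6.39 at the 114 sites), against 15.97 and 13.56 in replicates 1 and 2. Depth is unknown, so a difference between the lists beyond the cut-off stays open. Lower sensitivity of replicate 2 at all regions is argued against as the whole cause, since it called 20 of the 134 replicate 3 peaks on SOX2 regions where 29.3 to 32.0 were expected from all replicate 3 peaks of like fold (permutation p = 0.005 to 6e-05 with 2 to 10 bins of fold; 26.0 and p = 0.083 without matching). The replicate 3 peaks off SOX2 regions may be background, so poorer recovery of bound sites alone stays open for both replicates, and for replicate 1 so does lower sensitivity at all regions, with 17 called where 22.6 to 25.2 were expected (permutation p = 0.052 to 0.0018; 18.5 and p = 0.62 without matching). SOX2 material mixed into replicate 3 cannot be told apart from SOX15 binding at SOX2 sites, since both predict that the fold rises with SOX2 strength, and the test of that relation gave opposite signs in different sets of regions, with rho of -0.084 over 132 regions and 0.24 over 114.

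For that relation, over the 132 regions called in replicate 3, taken first, Spearman's rho of log2 fold with SOX2 replicates 1 and 2 was -0.026 (permutation p = 0.76) and -0.084 (p = 0.34), and Pearson's r was -0.10 (p = 0.26) and -0.29 (p = 0.00077). Over the 114 called there alone, a subset taken after that result was seen, rho was 0.20 (p = 0.034) and 0.24 (p = 0.0098), and r was 0.21 (p = 0.026) and 0.22 (p = 0.020). These are correlations across regions, which are not independent replicates; adjusted over the 4 relations, the r of -0.29 had p = 0.0031 and the last 2 rho p = 0.068 and 0.039. Without the 2 regions farthest from the median of SOX2 fold, r was -0.08 and -0.27 over the 132, and 0.20 and 0.28 over the 114.

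The lower number of SOX15 regions could come from SOX15 libraries that detect the strongest SOX2 sites alone. In that case nearly every SOX15 region would lie on a SOX2 peak, but 34.0% of the reproducible SOX15 regions overlapped no peak of either SOX2 library, above the 25% set beforehand. Also, 8 (4.0%) of the 200 SOX15 regions overlapped the 200 strongest SOX2 regions. Regions of 1 SOX15 library alone are left out of the 200 SOX15 regions by definition. Replicate 3 had a peak at 73 of 224 SOX2 regions (32.6%) of the strongest decile, away from snRNA, snoRNA and histone genes. Replicates 1 and 2 had 1 and 0 there, so the 4.0% cannot decide the question for replicate 3. The 34.0% argues against detection of the strongest SOX2 sites alone as the whole cause, for the reproducible regions as called. Of the 68 regions without a SOX2 peak 12 lay at clustered histone genes and 48 at none of the gene classes, and any of them may be background. Poorer detection of bound sites by the SOX15 libraries therefore stays open. The planned test of antibody background by SOX sites in the DNA was not run.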
